A study of Mus musculus with 8 samples.

How the data were processed

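RNA from dissected lateral ganglionic eminence of mouse embryos at embryonic day 14.5 was sequenced in 8 samples, 4 control (Dlx5/6-Cre with 1 floxed Meis2 allele) and 4 Meis2-CKO (Dlx5/6-Cre with 2 floxed alleles), per the labels. RNA was isolated with a column kit and libraries were made by standard Illumina protocols, per the labels' protocols. FastQC 0.11.5, HISAT2 2.1.0 and StringTie 1.3.1 and the mouse builds GRCm38.p2 and mm10 appear in the submitters' processing notes, without roles. The tool behind the fold changes and p-values is not given in the sources used here.

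The deposited data are 1 table of 16913 genes. Its mean expression signal per genotype was averaged over replicates by the authors, per the file headers; the header does not name the unit. The deposited signal values look length-scaled: over 5 bins of protein-coding genes by exon length, the median control value went from 9.18 in the shortest to 14.2 in the longest. The columns summed to 547952 in control and 543246 in Meis2-CKO. The log2 fold change of Meis2-CKO over control and the p-value with its adjusted form are the authors' deposited values, per the file headers. The adjusted p equals a Benjamini-Hochberg adjustment of the p-value over all 16913 genes. The sequencing depth is unknown, so no interval or detection floor is given, and a gene at exactly 0 is called only listed at 0.

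The table also has 8 columns of values per library whose names match no sample label. Columns were assigned by name only, not by order or by comparing values with the genotype means, so these were not used in any step. The tests planned before the data were examined (a model on counts or on log values of each library, set tests, other library scalings, a sex covariate, leaving out each sample, a replicate block) were therefore not run, by this choice. All statements on differences rest on the authors' deposited p-values at an adjusted p of 0.05, and no standard error, SD or replicate count is attached to them. For the same reason genes were not required to have non-overlapping groups, which the rule for named genes had asked. Other splits of the samples were not counted either. When the table was first opened, values of these columns were seen in 3 of its lines; no mapping was drawn from them.

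Gene places and exon lengths came from GENCODE M21 on GRCm38, the build named in the processing notes, matched by Ensembl gene ID for 16861 genes; 52 had no match. Genes of under 300 nt of exon were counted apart. For each of 20 gene lists fixed before the data were examined, and a list of sex-linked genes, members past the threshold were counted over all genes and adjusted over the list alone. The median log2 fold change of a list was placed among 10000 random lists of the same size, each member drawn from within 100 places in mean expression. That percentile describes these values and is no test across embryos. A further list of 30 genes of young neurons was written after the calls were seen and before its own values were. Gene Ontology terms in the table (10 to 500 tested genes) were tested with a one-sided Fisher exact test, with Benjamini-Hochberg adjustment over the terms. The background was the annotated genes whose higher mean reached the lowest such mean among the called genes.

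Genes were named by a rule fixed before the data were examined. It took Meis2, Dlx1, Dlx2, Six3 and Zfp503, then the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 and an official symbol. For each list except the sex-linked one it took up to 3 called members, or the 2 with the smallest p where none was called. The result for 1 gene is not reported here. Genes named outside it are said to be chosen after their values were seen or come with a count of a list. Alternatives were a mean of at least 2, a fold change of at least 1.5, a pseudocount of 1 and centring on the median. Added after the data were seen were a mean of at least 0.5, restriction to genes of 300 nt or more, to protein-coding genes or to genes above 0 in both genotypes, removal of Y-linked genes and Xist, the Benjamini-Yekutieli adjustment, and Gene Ontology terms without the copies of Cwc22.

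The procedures were tested on simulated data with the 16913 mean values of the comparison of Meis2-CKO with control. An exact binomial test recovered 71 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, and called 3 of 16713 unchanged genes. The simulated values held Poisson error only, with no spread between embryos. No call reported here came from that test, so these rates do not apply to the deposited calls. The matched-list percentile fell outside the central 95% for 11 of 200 lists with no shift and for 200 of 200 lists shifted by 0.5 on the log2 scale. For these lists the log2 fold changes were shuffled among genes. Lists whose members vary together were not simulated, and the rate may not apply to them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.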

Results

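The lateral ganglionic eminence (LGE) is the embryonic germinal zone and mantle that produce the projection neurons of the striatum. RNA was profiled from LGE dissected at embryonic day 14.5 from mice of 2 genotypes on a mixed C57BL/6J and CD1 background. In the 4 control samples, from littermates, 1 Meis2 allele was floxed and the Dlx5/6-Cre driver was present. In the 4 conditional knockout samples (Meis2-CKO) both Meis2 alleles were floxed and were recombined by the same driver, which is active in the Dlx-expressing cells of the ventral forebrain. Meis2 encodes a homeodomain transcription factor of the TALE class, and the series title names its dependence on Dlx1 and Dlx2 and its part in striatal neuronal fate. The values below are the authors' mean expression per genotype for 16913 genes, with their log2 fold change (Meis2-CKO over control) and p-values. The means carry no spread between embryos, the sequencing depth is unknown, and no test was run on individual libraries. The deposited p-values leaned high, with a median of 0.760, 80.2% of genes over 0.5 and 2.17% under 0.05. A gene that did not pass is therefore not shown to be unchanged. A comparison given at the end took 438 genes by fold change, not by small p. Of these, 95.9% had a deposited p within 10 times of an exact binomial p, and the others had a larger deposited p. Among called genes, Isl1 had a deposited p near its binomial p, while that of Meis2 was far larger than its binomial p. A very small p here need not reflect agreement between embryos.

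Meis2 itself was lower in the knockout. Meis2 in the authors' deposited table (ENSMUSG00000027210, chromosome 2, 115863064 to 116065839, GRCm38) had a mean of 204 in control and 140 in Meis2-CKO, and it fell by 0.53 on the log2 scale (adjusted p = 0.00195), short of the fold change of 1.5 tried as an alternative. The value sums over the whole gene, so transcripts that lack the floxed exons could still be counted, and cells outside the Dlx5/6 lineage keep both alleles; the remaining level is therefore no measure of recombination. The control carried 1 floxed allele with Cre and is not a wild type. Dlx1 in the authors' deposited table stood at 393 in control and 496 in Meis2-CKO (log2 fold change 0.35, adjusted p = 0.370), and Dlx2 at 137 and 171 (log2 fold change 0.34); neither passed. The 10 TALE-class relatives and partners of Meis2 held no gene past the threshold, with a median log2 fold change of 0.08. Pbx3 had authors' means of 69.4 and 79.9, and Meis3 of 54.0 and 48.3, in control and knockout.

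Several genes of direct-pathway striatal neurons were lower in the knockout. Isl1, a LIM homeodomain factor of these neurons, was 4.56-fold lower in the authors' deposited table (57.9 in control, 12.5 in Meis2-CKO, adjusted p = 7.8e-26). Ebf1, a helix-loop-helix factor of the same lineage, was 5.49-fold lower in the authors' deposited table (21.3 and 3.75, adjusted p = 1.34e-10), and Tac1, the substance P precursor, was 7.75-fold lower (15.6 and 1.89, adjusted p = 1.64e-09). Of 9 genes fixed for this group before the data were examined, 7 were listed and these 3 fell, both over all genes and adjusted over the list alone. The dopamine receptor Drd1 stood at 1.35 in control and 0.328 in Meis2-CKO (log2 fold change -1.69) and did not pass, and neither did Sfxn1 (21.6 and 21.2, log2 fold change -0.01) or Eya1 (1.83 and 2.70, log2 fold change 0.54). The median log2 fold change of the list was -1.69, at percentile 0 of 10000 random lists matched on expression.

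Transcription factors shared by both classes of striatal projection neuron were lower as well. Foxp1 in the authors' deposited table was 2.47-fold lower (40.2 in control, 16.1 in Meis2-CKO, adjusted p = 5.53e-08), the zinc-finger gene Zfp503 (Nolz1) 3.0-fold lower (22.5 and 7.35, adjusted p = 4.58e-06) and the retinoic acid receptor gene Rarb 5.63-fold lower (10.2 and 1.70, adjusted p = 5.14e-05). Bcl11b, which encodes CTIP2, also fell in the authors' deposited table (1.52-fold lower, adjusted p = 0.0013). All 20 genes of this pan-striatal list were listed, 18 had a log2 fold change below 0, and 5 fell at the threshold over all genes. Adjusted over the list alone, 9 fell, adding Ikzf1, Foxp4, Bcl11a and Foxp2. The median was -0.53, at percentile 0 of matched random lists. Bcl11b and these 4 were named after their values were seen. Ppp1r1b (12.6 and 11.2), Pde1b (24.6 and 26.9) and Rgs9 (2.97 and 3.24) had these means in control and Meis2-CKO in the authors' deposited table and did not pass.

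Genes of indirect-pathway neurons gave no call over all genes, although most had lower means. Six3, a homeobox gene needed for this class, stood at 25.5 in control and 16.7 in Meis2-CKO in the authors' deposited table (log2 fold change -0.59, adjusted p = 0.659). Adora2a, an adenosine receptor gene, stood at 5.18 and 1.84 in the authors' deposited table (adjusted p = 0.841), and the dopamine receptor Drd2 at 3.59 and 1.05. Of 8 fixed genes, 6 were listed; adjusted over the list alone, Six3, Adora2a and Drd2 passed as lower and Sp9, at 34.3 and 44.5, passed as higher. Grik3 stood at 39.1 and 38.4 (log2 fold change -0.01) and did not pass. Grik3 and Sp9 had the highest control means of the 6 listed genes, and neither was clearly lower. The list median of -1.01 lay at percentile 0. Six3os1, named after its value was seen, overlaps Six3 on chromosome 17 and fell in the authors' deposited table (25.1 and 12.8, adjusted p = 0.0102), a call lost under the Benjamini-Yekutieli adjustment, and strand is not stated for the counting, so the reads of the pair cannot be separated. Whether the direct and indirect lists differ from each other was not tested.

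**Figure D1:**
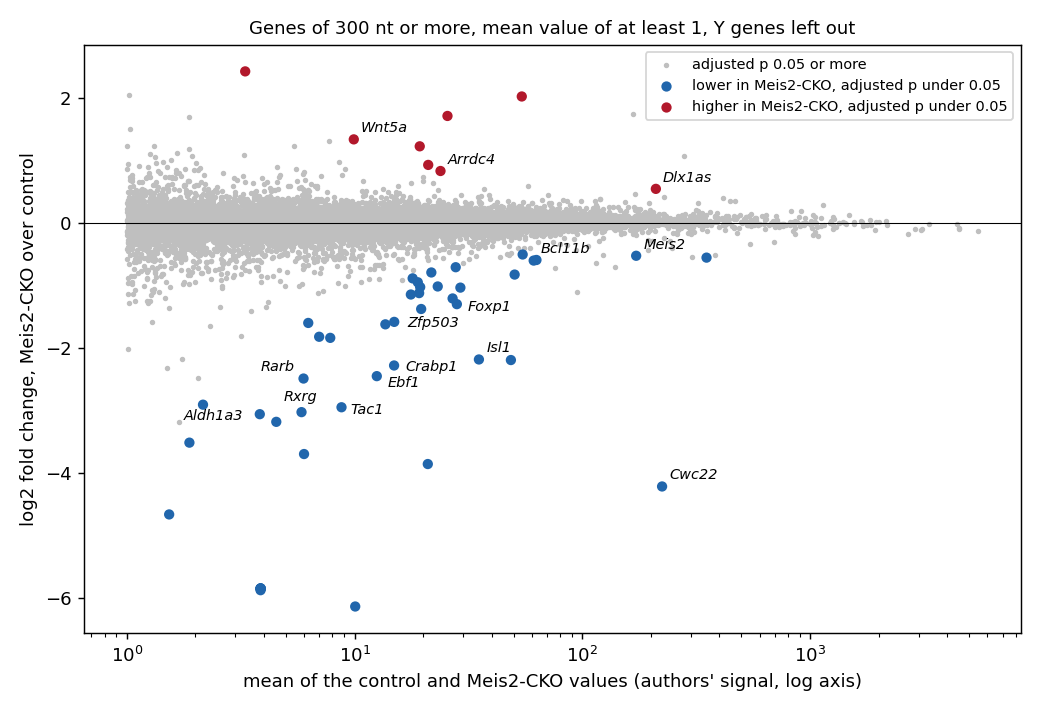
Log2 fold change of Meis2-CKO over control (vertical) against the mean of both genotypes (horizontal, log axis), both from the authors' deposited table, for genes of 300 nt or more with a mean of at least 1 and without Y-chromosome genes. Grey points did not pass adjusted p 0.05, blue points were lower and red points higher in the knockout; Isl1, at a log2 fold change of -2.19, Foxp1 at -1.30 and Meis2 at -0.53 lie below 0.

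Components of retinoic acid signalling were lower in part. Crabp1, a cytoplasmic retinoic acid binding protein, was 4.87-fold lower in the authors' deposited table (24.9 in control, 4.96 in Meis2-CKO, adjusted p = 2.34e-11). The receptor gene Rxrg was 8.18-fold lower in the authors' deposited table (10.5 and 1.17, adjusted p = 1.57e-06), and Aldh1a3, which encodes an enzyme of retinoic acid synthesis, 8.37-fold lower (6.96 and 0.715, adjusted p = 0.000279). Of 15 fixed genes 12 were listed, and these 3 fell whether adjusted over all genes or adjusted over the list alone. The list median was -0.12, at percentile 1.41.

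Progenitor and proliferation genes had slightly higher means without any single gene passing. Nes, the intermediate filament of neural progenitors, stood at 104 in control and 126 in Meis2-CKO (log2 fold change 0.29, adjusted p = 0.918), and Sox2 at 121 and 142 (log2 fold change 0.24), in the authors' deposited table. All 20 ventricular-zone genes had a log2 fold change above 0, with a median of 0.18 at percentile 100. The same held for all 30 cell-cycle genes, with a median of 0.20 at percentile 100; in the authors' deposited table Pcna stood at 290 and 356 (adjusted p = 0.332) and Cenpf at 25 and 33.6. Neither list had a member past the threshold, over all genes or adjusted over the list alone. The 30 genes of young neurons, a list written after the calls were seen, lay the other way, with 24 below 0 and a median of -0.12 at percentile 0; none passed over all genes, and adjusted over the list alone Stmn4, Ina and Gap43 passed as lower. The median log2 fold change of all 16913 genes was 0.01.

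Genes of GABAergic identity went both ways. Of 10 genes in the Dlx and GABAergic list 5 lay above 0 and 5 below, with a median log2 fold change of 0.04 (percentile 78.7). None was called over all genes, 5 had an unadjusted p under 0.05 in the authors' deposited table, and, adjusted over the list alone, Dlx1 and Dlx5 (72.3 in control, 92.1 in Meis2-CKO) passed as higher. Dlx6 stood at 39.8 and 29.9, Gad1 at 66.4 and 65.0, and Gad2 at 90.3 and 75.4, in the authors' deposited table. Among 10 genes of the dorsal LGE and its olfactory bulb interneurons none was called over all genes; adjusted over the list alone, Sp8 (17.3 and 26.8) and Vax1 (33.0 and 44.7) passed as higher, with a list median of 0.07 at percentile 88.4. Dlx1as, named after its value was seen, overlaps Dlx1 and rose over all genes in the authors' deposited table (172 and 249, 1.46-fold, adjusted p = 0.0131); this call was lost at a fold change of at least 1.5 and under the Benjamini-Yekutieli adjustment, and without a stated strand its reads cannot be separated from those of Dlx1.

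Markers of neighbouring territories and other cell types gave no calls in any list; the pairs of values that follow are the means of control and Meis2-CKO in the authors' deposited table. The 16 pallial glutamatergic genes had a median log2 fold change of 0.12 at percentile 99.7, with Neurog2 at 19.2 in control and 27.4 in Meis2-CKO and Eomes at 13.2 and 18.2. For 15 listed genes of medial and caudal eminence interneurons the median was 0.06 (percentile 88.7); Cxcr4 stood at 19.5 and 14.4 and Prox1 at 4.34 and 6.89. The 29 listed axon guidance genes had a median of 0.04 (percentile 78.3), with Robo2 at 37.8 and 27.1 and Ephb1 at 21.3 and 15.1. The medians were 0.07 for p53 targets (percentile 88.4; Sesn2 2.09 and 2.70, Mdm2 49.6 and 51.9) and 0.02 for immediate early genes (percentile 64.8; Npas4 1.63 and 1.02, Fos 0.445 and 0.240). For red blood cell genes the median was 0.05 (percentile 87.3), with Hba-a2 at 15.2 and 19.4 and Hbb-bt at 298 and 309; these globin genes have near-identical copies and their values are uncertain. Endothelial and pericyte genes had a median of 0.01 (percentile 53.5; Pecam1 6.53 and 7.51, Rgs5 12 and 12.7), and microglia and macrophage genes 0.01 (percentile 46.0; Cx3cr1 3.76 and 5.49, Aif1 3.82 and 2.89). Meningeal fibroblast genes had a median of -0.79 (percentile 0.4) at low levels, with Col1a2 at 1.82 and 0.802 and Dcn at 0.475 and 0.090. Oligodendrocyte lineage genes had a median of -0.03 (percentile 43.7; Sox10 0.515 and 0.310, Mbp 6.07 and 5.61). Only 2 of 6 choroid plexus genes were listed, Kcnj13 at 0.035 and 0.355 and Otx2 at 7.78 and 7.50, with a median of 0.78 (percentile 87.3).

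**Figure D2:**
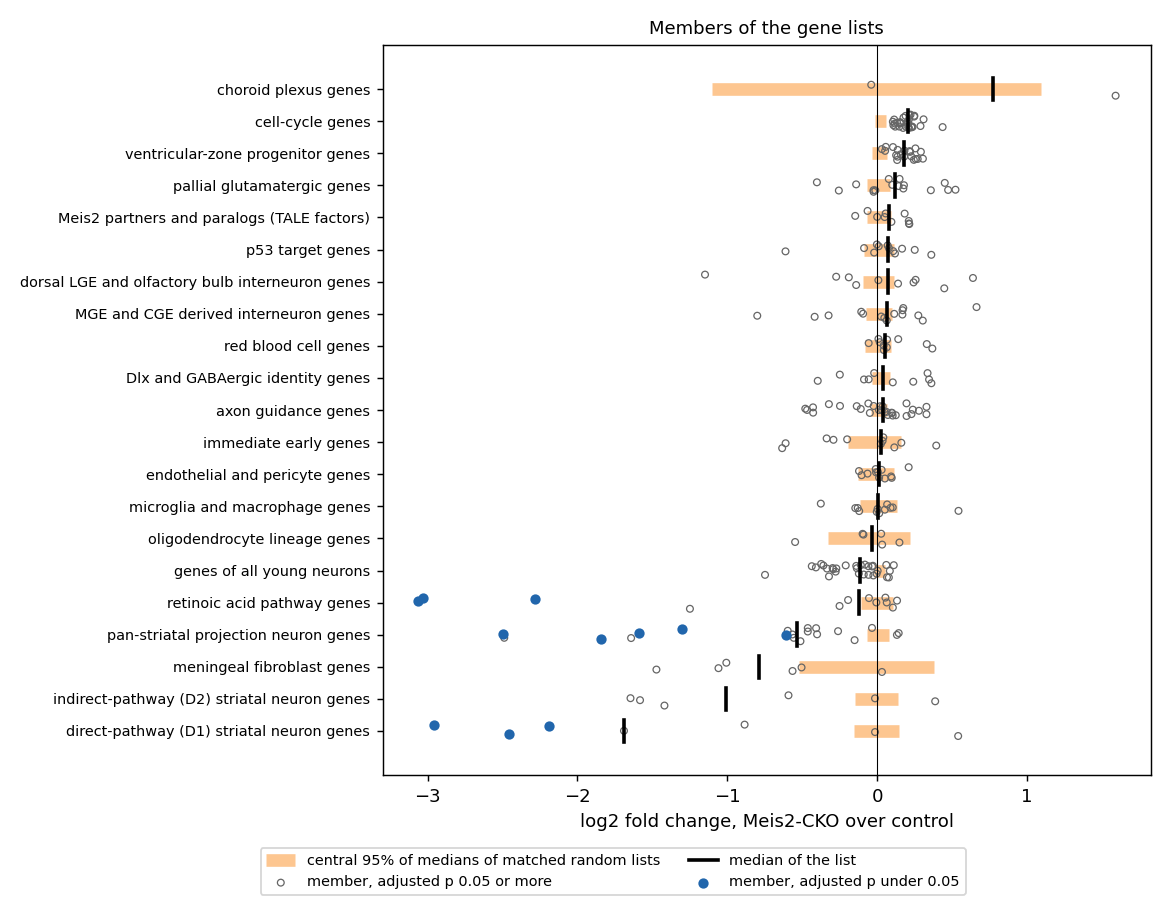
Log2 fold change of Meis2-CKO over control for the members of each gene list, from the authors' deposited table. Filled points passed adjusted p 0.05 over all genes, open points did not, black bars mark list medians and orange bands the central 95% of medians of matched random lists; the direct-pathway list has its median at -1.69 and the cell-cycle list at 0.20.

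The sex-linked genes differed between the genotype means. In the authors' deposited table the Y-chromosome genes Eif2s3y (50.5 in control, 14 in Meis2-CKO), Ddx3y (14.1 and 4.03) and Kdm5d (13.1 and 4.09) fell, and Uty stood at 6.60 and 2.36. Xist, expressed from the inactive X chromosome, stood at 78.0 and 256 in the authors' deposited table (log2 fold change 1.74, adjusted p = 0.985). The labels give no sex for the embryos, and these values stand beside every difference between the genotypes reported here.

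Over the whole of the authors' deposited table, 132 of 16913 genes passed an adjusted p of 0.05, 40 higher and 92 lower in the knockout. Of these, 74 were genes of under 300 nt, among them 36 of 70 small nucleolar RNAs and 13 of 28 microRNA genes, and 66 were listed at 0 in 1 of the genotypes. By the fixed rule the largest rises were those of Mir8091 (mean 15.5 in Meis2-CKO), Snora28 (11.5), Mir1839 (11.2), Snora7a (7.40) and Snora68 (3.39), each listed at 0 in control in the authors' deposited table. The largest falls were those of Snora17 (33.2 in control), Snord22 (24.4), Snora41 (12.5), Snora31 (7.90) and Scarna8 (6.61), each listed at 0 in Meis2-CKO. Of genes of 300 nt or more, 57 of 16451 passed (0.346%), 8 higher and 49 lower, and 37 of these carried a symbol other than Gm or Rik and lay outside the Y chromosome, 4 higher and 33 lower. Adjusted again among genes of 300 nt or more, a choice made after the short genes were seen, 51 passed. The mean values give no spread between libraries with which to judge the short genes.

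Of 13612 protein-coding genes of 300 nt or more, 46 were called, 4 higher and 42 lower. Some of those beyond the fixed lists are named here, after their values were seen. The lower ones include the near-identical copies of Cwc22 described below and the Y-chromosome genes Eif2s3y, Ddx3y and Kdm5d. Pcna-ps2, a pseudogene by its symbol (39.4 in control, 2.57 in Meis2-CKO), and Eif3j2 (8.28 and 0.79) were among them too. In the authors' deposited table Plk2, a stress-responsive kinase gene, was 2.32-fold lower (37.8 in control, 16.1 in Meis2-CKO) and Vstm2a 3.09-fold lower (20.7 and 6.58). Both subunit genes of soluble guanylate cyclase fell, Gucy1a3 2.05-fold (39.4 and 18.9) and Gucy1b3 1.74-fold (27.7 and 15.8). The neurofilament genes Nefl (11.0 and 2.99) and Nefm (26.2 and 12.7) fell, although their annotated spans on chromosome 14 overlap, and L1cam, a neural adhesion gene, was 1.51-fold lower (76.0 and 49.8). Scg5 (64.8 and 36.1), Syt6 (26.5 and 12), Tspan9 (24.5 and 10.9), Rgs2 (34.7 and 20.9) and Socs2 (23.5 and 12.5) were lower too. Wnt5a, a secreted ligand, was 2.52-fold higher in the authors' deposited table (5.62 and 14.2, adjusted p = 0.0106), and Arrdc4 was 1.78-fold higher (17.2 and 30.5, adjusted p = 0.0133). The calls of Gucy1b3, Rgs2 and Socs2 were lost when genes of 300 nt or more were adjusted again, and these and the calls of Wnt5a and Arrdc4 were lost under the Benjamini-Yekutieli adjustment.

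The called gene with the highest control mean on chromosome 2 was Cwc22, which encodes a splicing factor; it and its copies were chosen after their values were seen. Cwc22 (77881159 to 77946375) stood at 426 in control and 22.5 in Meis2-CKO, 18.7-fold lower in the authors' deposited table (adjusted p = 1.31e-07). The 6 predicted genes between 83955693 and 83993045, namely Gm13691, Gm13693, Gm13694, Gm13696, Gm13697 and Gm13698, each had a control mean of 7.73 and a knockout mean of at most 0.01. These are near-identical annotated copies, so their values and that of Cwc22 are uncertain where reads were shared. The gene lies on the same chromosome as Meis2.

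**Figure D3:**
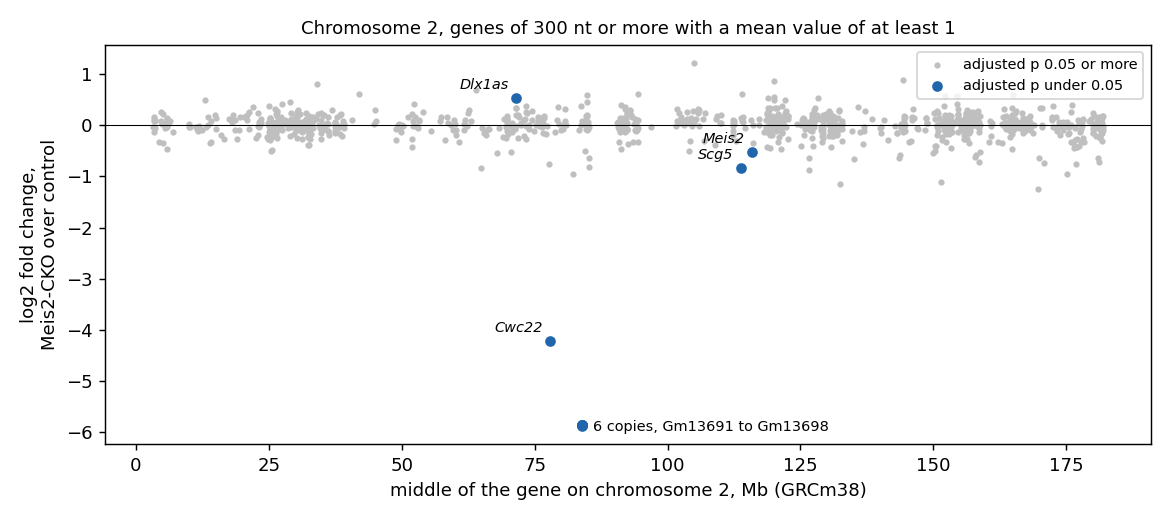
Log2 fold change of Meis2-CKO over control (vertical, from the authors' deposited table) along chromosome 2 (horizontal, Mb, GRCm38), for genes of 300 nt or more with a mean of at least 1. Blue points passed adjusted p 0.05: Cwc22 lies at -4.22, its 6 copies together near -5.86, Scg5 at -0.83, Meis2 at -0.53 and Dlx1as at 0.54.

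Gene Ontology terms carried by the table gave few enrichments. Among lower genes of 300 nt or more, 3 terms passed. The catalytic step 2 spliceosome and mRNA splicing terms (7 genes each, Fisher exact test, adjusted p = 0.000117 for both) consisted of Cwc22 and its 6 copies. The neuropeptide signaling pathway term, which does not contain them, passed too (3 of 18 tested genes, Fisher exact test, adjusted p = 0.0321). With the 6 copies left out, a step added after the terms were seen, no term passed. The neuropeptide signaling pathway term, with the same 3 genes, then had an adjusted p of 0.0597 (Fisher exact test). Its unadjusted p was 4.29e-05 with the copies and 2.66e-05 without them (Fisher exact test). The adjusted p rose because the splicing terms no longer ranked ahead of it. Over genes of every length, the higher genes gave 1 term, the small nucleolar ribonucleoprotein complex (Snora64 and Snora68, 2 of 10 tested genes, Fisher exact test, adjusted p = 0.0478).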

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

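The alternatives other than a mean of at least 2, a fold change of at least 1.5, a pseudocount of 1 and centring on the median were chosen after the data were seen. The 98 results were counts and the genes named by the fixed rule, so lost calls of other genes given below are not among them. Over 98 results and 10 alternatives, 939 values were computed, fewer than every combination because some genes fell outside a restriction. Of these, 929 stayed on their side of the threshold, or for counts within 1.5 times, 9 moved and 1 (Meis2) lost its call. This is no measure of stability: 196 values, from the pseudocount and the centring, could not change a call, and adjusting again cannot change a direction. The count of called genes (132, with 40 higher and 92 lower) moved most where a restriction left out many of the called genes themselves, 74 of which are under 300 nt. It was 51 (8 higher, 43 lower) for genes of 300 nt or more, 40 (4 higher, 36 lower) for protein-coding genes and 60 (15 higher, 45 lower) for genes above 0 in both genotypes; all of these genes were among the 132. Rph3a, Klhl13, Socs2, Rgs2, Ppm1j and Gucy1b3 entered the first of these and lost their call, with adjusted p of 0.0605 to 0.0955. Meis2, with a log2 fold change of -0.53, did not reach a fold change of 1.5, nor did Meg3 (-0.56), Dlx1as (0.54) and Klhl13 (-0.51). Under the Benjamini-Yekutieli adjustment the 6 genes from Rph3a to Gucy1b3, Wnt5a, Arrdc4, Dlx1as and Six3os1 were among the 26 lost. The count was 113 at a mean of at least 2, 128 at a fold change of at least 1.5, 133 at a mean of at least 0.5, 128 without Y-linked genes and Xist and 106 under the Benjamini-Yekutieli adjustment. Not run, because library columns were not assigned to genotypes by their values, were other count tools and scalings, quantile normalization, a pseudocount of 0.1, a sex covariate, camera, fry and leaving out each sample. No paired analysis was possible because the library columns carry no replicate number. At low levels only large changes were called: among genes of 300 nt or more the smallest absolute log2 fold change called was 2.42 at means of 1 to 5 and 0.89 at 5 to 20.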

Other observations

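The tests of count-like p-values, of shared reads, of fewer neurons of all kinds as the whole cause and of calls near Meis2 without Meis2 itself were chosen after the results were seen. In the authors' deposited table, genes of the imprinted Dlk1 to Meg3 region of chromosome 12 had lower means in the knockout, an observation picked after the values were seen. Dlk1, a paternally expressed Notch-related gene, was 2.60-fold lower in the authors' deposited table (28.5 in control, 10.8 in Meis2-CKO, adjusted p = 3.32e-06), and the maternally expressed noncoding RNA Meg3 was 1.47-fold lower (420 and 283, adjusted p = 0.00465), short of the fold change of 1.5 tried as an alternative. Rian stood at 360 and 246 in the authors' deposited table (adjusted p = 0.135) and Mirg at 16.2 and 11.2 (log2 fold change -0.52), neither past the threshold. Npas1, a transcription factor gene, stood at 5.75 and 11.3 (log2 fold change 0.97), also not past it.

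Striatal projection neuron lists lay below 0, and 8 of 33 listed members were called as lower over all genes. Members below 0 were 6 of 7 in the direct-pathway list, 5 of 6 in the indirect-pathway list and 18 of 20 in the pan-striatal list. The medians over all listed members were -1.69 for the direct-pathway list, -1.01 for the indirect-pathway list (none called over all genes, Sp9 above 0) and -0.53 for the pan-striatal list. Genes of all young neurons (30 genes, 24 below 0) had a median of -0.12 (percentile 0), with a bootstrap interval over genes of -0.27 to -0.05, while progenitor and cell-cycle genes had medians of 0.18 and 0.20. The median of all 33 striatal members lay below that of the young neuron genes. The difference was -0.48 (bootstrap interval over genes -1.35 to -0.27). In these genotype means this argues against fewer neurons of all kinds as the whole cause. The comparison was chosen after the results were seen, and its interval holds no spread between embryos. A smaller neuron share with more progenitors, or a loss of striatal neurons in particular, could still contribute. A lower share of striatal cells with more pallial and medial tissue cannot be told apart from altered gene expression: the lower of the pallial and medial list medians was 0.064, with an interval of -0.11 to 0.17. A biological hypothesis that Meis2 loss reduces striatal differentiation stays open beside it, as does a difference in sex between the genotype means.

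Short genes made up 74 of the 132 calls. A candidate explanation is that p-values were computed as if the length-scaled values were counts, which understates the error of short genes. Of the 74, 64 were listed at 0 in 1 genotype. The comparison that follows needed at least 1 in both genotypes, so it left these 64 out. In 438 genes with at least 1 in both genotypes and an absolute log2 fold change of at least 0.5, 0% had a deposited p more than 10 times below an exact binomial p of 4 times the means, also among the 256 of at least 2000 nt, and 95.9% lay within 10 times of it. The other 18 genes had a larger deposited p, among them Meis2 (exact binomial 1.65e-11, deposited 1.08e-05) and Xist (9.53e-90 and 0.0136). The deposited p-values were thus not purely those of counting error. A p cannot exceed 1, so genes with a large exact binomial p could not have lain more than 10 times above it. The share within 10 times therefore says little about very small p-values. Among striatal calls, Isl1 had an exact binomial p of 1.18e-28 and a deposited p of 4.15e-29. Among called short genes, Gm38671, listed at 0 in control, had an exact binomial p of 4.78e-57 and a deposited p of 4.02e-57. A very small deposited p therefore need not reflect agreement between embryos, for short or long genes. The 51 called short genes with a host gene argue against changed transcription of host genes, with a median signed host log2 fold change of -0.0094 (bootstrap interval -0.029 to 0.009) and 0 hosts called; whether the short RNAs differ between embryos stays open.

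On chromosome 2, Cwc22 and its 6 copies fell on the Meis2 chromosome. The 6 copies list the same control mean, which is consistent with reads shared among near-identical copies and leaves them as 1 observation. The copy number of Cwc22 differs among mouse strains, and on a mixed background a haplotype around the floxed Meis2 allele could carry another copy number. With the family counted once, 4 of 51 called genes of 300 nt or more lay within 50 Mb of Meis2, against 4.48% of tested genes (one-sided Fisher exact p = 0.193), and without Meis2 itself p was 0.388. With each copy counted, 10 of 57 lay there, against 4.51% (one-sided Fisher exact p = 0.000207). As the copies are 1 observation, this last test counts 1 signal several times. The test with the family counted once is the one that applies. With so few calls, a haplotype effect cannot be told apart from an effect of Meis2 loss.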
